A study of Homo sapiens with 8 samples.

How the data were processed

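RNA-seq gene counts were analysed for 8 libraries of the human lung adenocarcinoma line H2009, in 4 groups of 2. The groups were control cells, cells given siRNA against PXN, cells given siRNA against ITGB4, and cells given both. Per the labels, the ITGB4 and PXN siRNAs came from different suppliers, were delivered with jetPRIME in 6-well plates at 10 nM, and RNA was taken 72 h later with an RNeasy Plus kit that includes a DNase step. The labels say that the experiment was done 2 times. The treatment of the control cells, the siRNA sequences, the strandedness of the libraries and the dose per siRNA in the double transfection are not given in the sources used here.

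The deposited table holds raw read counts per gene, with no normalization, beside hg19 gene coordinates and a gene length that the file header gives in kilobases. Per the labels, the authors used bcl2fastq 2.18.0.12, STAR 2.6.0, HTSeq 0.6.0 and edgeR 3.28.1 with genome build hg19, and the role of each tool is not stated. The table was checked to hold whole numbers with a different total in each library. All 8 columns were matched to a sample. Total counts ran from 21786604 to 25087192, and the 100 most abundant genes took 11.8% to 13.0% of them. A count of 0 allows up to 3 counts, or 0.120 to 0.138 CPM depending on the library. These limits cover counting error only, since the reads carry no molecular identifiers.

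Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of 23354 genes, 14208 were tested after filterByExpr with a minimum count of 10, and 9146 were left out. Libraries were scaled by TMM factors, and CPM values use these factors. A quasi-likelihood model with 4 group means was fitted to all 8 libraries, with the newer edgeR 4 form of the dispersion estimate set explicitly, since the legacy form is the default of this release. Each of 7 comparisons was a contrast in that model, tested two-sided, with Benjamini-Hochberg adjusted p below 0.05 counted as changed. The 7 were each siRNA treatment against control, both siRNAs against each single siRNA, the single siRNAs against each other, and the interaction, which compares the effect of the ITGB4 siRNA with and without the PXN siRNA. Errors of log2 fold changes are standard errors from the model and errors of CPM are standard deviations over 2 libraries.

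Replicate numbers were checked for pairing. After removal of group means, libraries of the same number in different groups correlated at 0.699 to 0.804 across genes in all 6 pairs of groups, and the first principal component separated numbers 1 and 2. A model with the replicate number as an additive block was planned as an alternative. Its biological coefficient of variation was 7.58%, against 23.4% without the block, with 3 and 4 residual degrees of freedom. That the numbers mark the 2 experiments is an assumption, not given in the sources used here. The model without the block had been fixed before the data were examined and was kept, and the value with the block is given where it changes a call or count.

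The model, the comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the 10 genes with the largest rise and the 10 with the largest fall in each comparison with control, and 5 and 5 in the other comparisons. A gene had to pass the adjusted p, reach a mean of 2 CPM in the higher group, have both libraries of one group on the same side of both libraries of the other, and carry a symbol that is not a clone name. ITGB4 and PXN are named throughout. USP1 and VDAC1 are named because the study followed them up, so their changes are not independent evidence. Each list adds up to 4 members with the smallest adjusted p. Where the model without the block called no gene, the rule was applied to the model with the block, a choice made after seeing the data.

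The 32 lists cover focal adhesion adaptors and kinases, other integrin subunits, hemidesmosome and laminin genes, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and senescence, p53 targets, Fanconi anaemia repair, nucleotide excision repair and platinum transport. They also cover NRF2 targets, mitochondrial apoptosis, oxidative phosphorylation, glycolysis and hypoxia, stress and unfolded protein responses, interferon, NF-kB, epithelial junctions, mesenchymal genes, YAP/TEAD targets, SRF and actin genes, RAS/ERK output, MYC and ribosome biogenesis, cholesterol synthesis, proteasome subunits, ribosomal proteins, histones and mitochondrially encoded genes. Markers of lung lineages, leukocytes, fibroblasts and endothelium complete them. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The 31 lists with at least 3 tested members could be tested; none of the 15 mitochondrially encoded genes is in the table.

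Alternatives were DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood form, median-of-ratios and upper-quartile scaling, no filter, a minimum count of 50, the replicate block, a model with only the groups compared, an adjusted p below 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. A lone library left in a group is assumed to vary like the other groups. The leave-out fits have no block. A group left with 1 replicate number thus carries the difference between the numbers into its comparisons. Lost calls, ranges and reversals in these fits do not measure the number of libraries alone.

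Words of 7 bases were searched in the longest annotated 3' UTR of each gene in GENCODE release 29, matched by symbol, older symbol or unique synonym. This annotation is on another build than the counts, so it supplied sequence and no coordinates. Of the tested genes, 13156 (92.6%) had a 3' UTR of at least 50 bases; the other 1052 were not searched. For each of 16329 words, the difference in log2 fold change between genes with and without it was estimated after adjustment for 3' UTR length, GC content and mean expression. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the words and matplotlib 3.10.9 for the figures.

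The models were tested on simulated data, in which a known set of genes was changed. Dispersions and replicate shifts were those estimated with the block. The data thus follow the model with the block, and the shares recovered are no neutral comparison of the 2 models. In the 6 comparisons of groups, the model without the block recovered 0% of 1.5-fold, 11.9% to 17.9% of 2-fold and 51.5% to 75.8% of 4-fold changes, with 0 false calls. The model with the block recovered 58.2% to 71.6%, 79.1% to 89.6% and 93.9% to 98.5%, with 13 to 17 false calls among 168 to 187 calls. For the interaction these shares were 0%, 0% and 21.2% without the block, with 0 false calls, and 31.3%, 67.2% and 84.8% with it, with 12 false calls. In 10 simulated draws without any change, camera called 1 list in all, the G2/M list. With the G2/M list lowered 2-fold it called that list in 10 of 10 draws. The simulation draws genes independently, so it does not test the preset correlation.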

Results

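Gene expression was measured by RNA-seq in H2009, an established human lung adenocarcinoma cell line derived from a lymph node metastasis. The 8 libraries form 4 groups of 2: control cells, cells given siRNA against PXN, cells given siRNA against ITGB4, and cells given both. PXN encodes paxillin, an adaptor of focal adhesions, and ITGB4 encodes integrin beta 4, the hemidesmosome integrin. The title of the series places these genes on an axis that bears on chemoresistance in lung cancer. RNA was collected 72 h after transfection of 10 nM siRNA. The libraries held 22949271 and 21786604 counts in control cells, 24040646 and 22871382 after PXN siRNA, 24316564 and 25087192 after ITGB4 siRNA, and 24500309 and 24135814 after both. Values are TMM-scaled CPM (mean ± SD, n = 2) and log2 fold changes ± SE from edgeR over 14208 tested genes. The p-values measure the spread between these libraries, from an experiment done 2 times in one line.

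Along the first principal component, with 44.1% of the variance, the libraries separated by replicate number and not by siRNA. The second, with 24.8%, parted cells that received ITGB4 siRNA from those that did not, and the third, with 19.8%, parted cells with and without PXN siRNA. Replicates of a group correlated at 0.976 to 0.978 across genes.

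**Figure D1:**
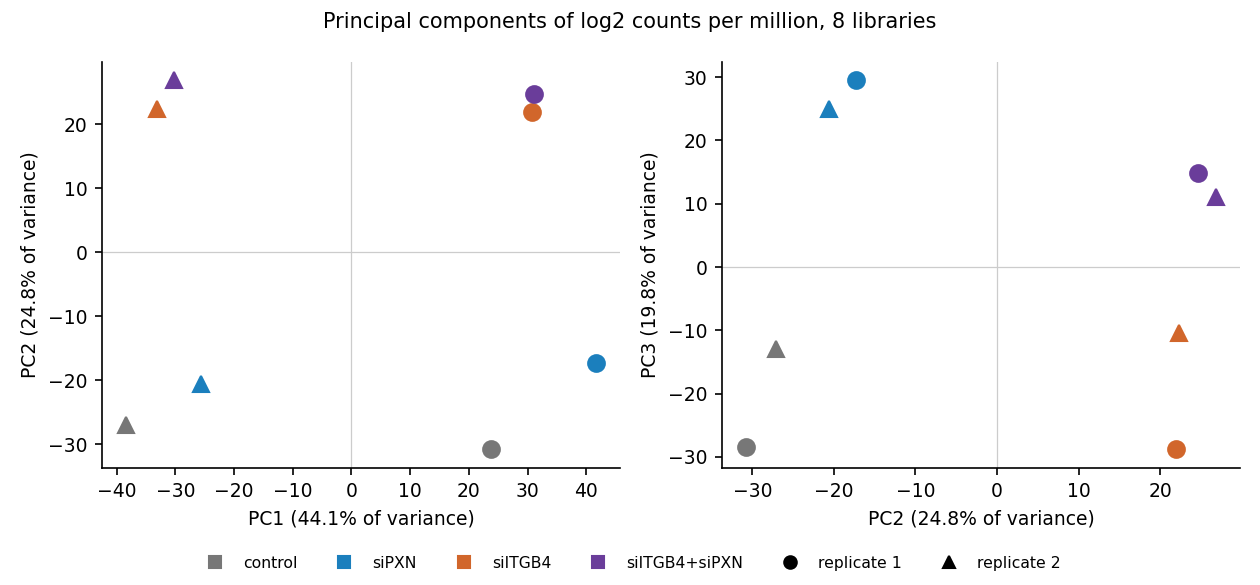
Principal components of log2 CPM for the 8 libraries, with groups by colour and replicate number by symbol. The left panel shows PC1 (44.1% of variance) against PC2 (24.8%), the right panel PC2 against PC3 (19.8%), and PC1 separates replicates 1 and 2 in each of the 4 groups.

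Each siRNA lowered its target. ITGB4 (17:73717516-73753899, plus strand) stood at 459 ± 111 CPM in control cells and at 121 ± 6.73 after its siRNA (log2 fold change -1.92 ± 0.26, adjusted p = 0.0271), which left 23.4% and 30.5% of the level in the control library of the same number. After both siRNAs it stood at 120.4 ± 14.6 CPM (log2 fold change -1.93 ± 0.26, adjusted p = 0.0172). PXN (12:120648242-120703574, minus strand) went from 322 ± 86.9 CPM to 55.6 ± 8.68 after its siRNA, 16.1% and 19.0% of the matching control library. That value missed the threshold without the replicate block (log2 fold change -2.53 ± 0.27, adjusted p = 0.0617) and passed it with the block (log2 fold change -2.52 ± 0.16, adjusted p = 1.9e-04). After both siRNAs PXN fell to 31.1 ± 3.64 CPM (log2 fold change -3.37 ± 0.28, adjusted p = 0.00659), 7.44% and 12.9% of control. The ITGB4 call was lost without either control, siITGB4 or double-siRNA library, at a log2 fold change of -2.15 to -1.65. These fits have no block. A group left with 1 replicate number then carries the difference between the numbers into its comparison, so the loss cannot be put down to the number of libraries alone. After both siRNAs the ITGB4 call was lost without control replicate 1 (adjusted p = 0.0941) and without siITGB4+siPXN replicate 1 or 2 (0.107 and 0.108), and the PXN call without siITGB4+siPXN replicate 1 or 2 (0.0697 and 0.0570).

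Neither siRNA lowered the other target. ITGB4 read 597 ± 178 CPM after PXN siRNA (log2 fold change 0.38 ± 0.25, adjusted p = 0.540), a rise only with the replicate block (log2 fold change 0.37 ± 0.11, adjusted p = 0.0345). PXN read 324 ± 83.3 CPM after ITGB4 siRNA (log2 fold change 0.01 ± 0.25, adjusted p = 0.993). Of the genes the study followed up, VDAC1 (5:133307566-133442104, minus strand), a channel of the mitochondrial outer membrane, fell from 206 ± 49.3 to 52.1 ± 10.7 CPM after ITGB4 siRNA (log2 fold change -1.98 ± 0.22, adjusted p = 0.0185) and to 41.3 ± 3.86 after both (log2 fold change -2.32 ± 0.22, adjusted p = 0.00751). The first call was lost without either control, siPXN or siITGB4 library, the second without control replicate 1 or either siITGB4+siPXN library. After PXN siRNA it stood at 158 ± 13.8 CPM (log2 fold change -0.38 ± 0.21, adjusted p = 0.467; with the block log2 fold change -0.36 ± 0.09, adjusted p = 0.0179). USP1 (1:62901975-62917475, plus strand), the deubiquitinase of the Fanconi anaemia pathway, fell from 290.2 ± 55.0 to 116 ± 9.80 CPM after both siRNAs (log2 fold change -1.33 ± 0.21, adjusted p = 0.0244), a call lost without either control or either siITGB4+siPXN library. It stood at 146 ± 34.1 CPM after ITGB4 siRNA (log2 fold change -0.99 ± 0.21, adjusted p = 0.0808; with the block log2 fold change -0.99 ± 0.09, adjusted p = 1.0e-04) and at 203 ± 21.4 after PXN siRNA (log2 fold change -0.51 ± 0.21, adjusted p = 0.310; with the block log2 fold change -0.50 ± 0.09, adjusted p = 0.00370). The 3' UTR of VDAC1 holds 1 copy of the word GAGTATG described below, that of USP1 none.

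**Figure D2:**
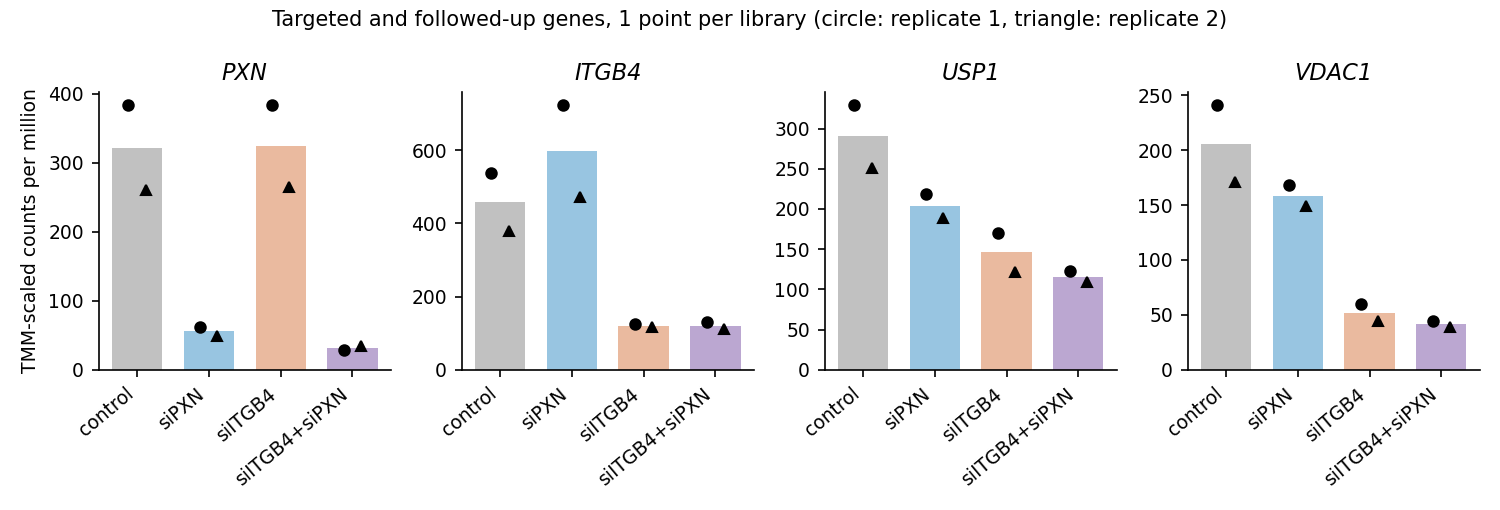
TMM-scaled CPM of PXN, ITGB4, USP1 and VDAC1 in each of the 8 libraries (circles, replicate 1; triangles, replicate 2), with bars at the group mean of 2 libraries. PXN is at 28.5 to 61.7 CPM in the 4 libraries with PXN siRNA and ITGB4 at 110.1 to 131 CPM in the 4 with ITGB4 siRNA.

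The comparison of ITGB4 siRNA with control asks what loss of the integrin alone does. G3BP1 (5:151151476-151184915, plus strand), which nucleates stress granules, fell most, from 409 ± 20.5 to 57.3 ± 8.79 CPM (log2 fold change -2.83 ± 0.14, adjusted p = 0.00398). The leptin receptor LEPR fell from 56.7 ± 6.18 to 8.46 ± 0.884 CPM (log2 fold change -2.74 ± 0.15, adjusted p = 0.00554) and TMEM30A, a subunit of lipid flippases, from 366 ± 92.1 to 65.0 ± 0.579 CPM (log2 fold change -2.49 ± 0.19, adjusted p = 0.0102). SLAIN1, NXPE3, ARL6IP6, the mitochondrial carrier SLC25A30, the branched-chain keto acid dehydrogenase subunit DBT, MESDC1 and the actin-binding TWF1 complete the 10 largest falls, with log2 fold changes of -2.74 to -2.08. Among the genes that rose, the interleukin 6 receptor IL6R went from 41.2 ± 9.94 to 184 ± 49.4 CPM (log2 fold change 2.16 ± 0.31, adjusted p = 0.0314) and the pro-apoptotic BMF from 17.1 ± 5.44 to 50.9 ± 6.59 CPM (log2 fold change 1.57 ± 0.26, adjusted p = 0.0427).

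The largest rise in that comparison was in ANKRD35 (2.73), at 0.588 CPM in control cells. GOLGA7B, CHST2, the channel TRPV3, the co-stimulatory ligand ICOSLG, ARRDC4, GPR153 and the transcription factor BACH2 followed, with log2 fold changes of 1.40 to 1.53. In all, edgeR called 245 genes, of which 53 rose and 192 fell, and 23 and 124 of these did so at least 2-fold. With the replicate block it called 3965 genes, 1905 up and 2060 down, which include all 245 in the same direction, and DESeq2 called 936. Without any 1 of the 8 libraries the count lay between 1 (without siITGB4 replicate 1) and 55 (without siITGB4+siPXN replicate 1), and of the 20 genes named by size 1 to 7 stayed past the threshold.

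A short sequence was over-represented among the falling genes. Of the 188 with a searched 3' UTR, 97 (51.6%) held the 7-base word GAGTATG, against 0 of 52 rising genes and 7.84% of genes not called. With the block it was held by 434 of 1973 falling genes, 73 of 1857 rising genes and 602 of 9326 genes not called. Among the 10 largest falls, 6 held it, with 3 copies in G3BP1 and 2 in TMEM30A, while LEPR held none. Of the 10, 9 held GAGTATG or a second word, GACAACT, described in the closing section, and LEPR held neither. Both words were selected in this comparison, GAGTATG as the most negative of 16329, and the closing section gives the independent test of each.

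In the fixed lists, G2/M genes were lower after ITGB4 siRNA, less so in replicate 2, and G1/S genes had no common direction. The G2/M list had a mean log2 fold change of -0.43 over 31 genes (camera adjusted p = 3.0e-05, and adjusted p = 0.962 with an estimated correlation). In replicates 1 and 2 the G2/M mean was -0.64 and -0.23, with 30 and 22 members lower than in the matching control library, and the G1/S mean 0.17 and -0.09, with 7 and 23 lower. The G1/S list had a mean of 0.05 over 34 genes (adjusted p = 0.588, and adjusted p = 0.962 with an estimated correlation), with 5 that rose and 3 that fell with the block. The mitotic kinase AURKA fell from 121 ± 17.1 to 31.7 ± 3.14 CPM (log2 fold change -1.94 ± 0.26, adjusted p = 0.0283) and cyclin A2, CCNA2, from 177 ± 22.2 to 77.6 ± 0.914 (log2 fold change -1.19 ± 0.18, adjusted p = 0.0350). These were the 2 G2/M members called among all genes. When adjusted over the list alone 4 fell, and with the block 13 fell and 15 adjusted over the list alone. The 5 G2/M members with GAGTATG or GACAACT had a mean of -0.99. The 26 without either had a mean of -0.32, and 9 of them fell with the block. The YAP/TEAD list (-0.45, adjusted p = 0.00808, and adjusted p = 0.962 with an estimated correlation) had 0 called members and 0 adjusted over the list alone, with 11 that fell and 1 that rose with the block; its member AJUBA stood at -1.12 (adjusted p = 0.150, with the block 1.7e-04). The 5 YAP/TEAD members with an ITGB4 siRNA word, GAGTATG or GACAACT, had a mean of -0.66. The 18 without one had a mean of -0.39, with 6 that fell and 1 that rose with the block. After both siRNAs, members with and without a word of either siRNA had means of -0.43 and -0.45. Histone genes (-0.68, adjusted p = 0.0321, and adjusted p = 0.962 with an estimated correlation) had 0 called members by either adjustment and 8 that fell with the block. The YAP/TEAD call was lost without siITGB4 replicate 2 and the histone call without siITGB4 replicate 1 or control replicate 2.

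Single members of other lists also passed after ITGB4 siRNA. The cystine transporter SLC7A11 fell (log2 fold change -1.42 ± 0.22, adjusted p = 0.0389), as did the guanine nucleotide exchange factor DOCK1, a partner of the paxillin-binding adaptor CRK (log2 fold change -0.99 ± 0.11, adjusted p = 0.0217), and the ribosomal protein gene RPL11 (log2 fold change -0.95 ± 0.14, adjusted p = 0.0317). The lysosomal glycoprotein gene CD68 rose from 8.56 ± 0.648 to 20.9 ± 0.854 CPM (log2 fold change 1.29 ± 0.21, adjusted p = 0.0427). The copper transporter SLC31A1, which also carries cisplatin, stood at 94.8 ± 15.1 and 161 ± 12.3 CPM (log2 fold change 0.77 ± 0.15, adjusted p = 0.0691; with the block log2 fold change 0.77 ± 0.08, adjusted p = 2.6e-04).

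With PXN siRNA, the comparison with control asks what loss of paxillin alone does, and its genes are named from the fit with the replicate block. In that fit the cargo receptor TMED2 fell from 499 ± 40.4 to 99.9 ± 3.84 CPM (log2 fold change -2.32 ± 0.17, adjusted p = 2.2e-04) and S100A10, the annexin A2 partner, from 1142 ± 404 to 270.2 ± 108 CPM (log2 fold change -2.09 ± 0.11, adjusted p = 1.2e-04). The cathepsin gene CTSO (-2.88), the retinal dehydrogenase ALDH1A3 (-2.00), OSTM1, the polymerase III subunit POLR3G, the gamma-tubulin complex gene MZT1, the repair gene RMI2 and the import channel subunit TIMM17A fell as well, the last 5 by log2 fold changes of -1.89 to -1.76. TAGLN, the smooth muscle protein transgelin, rose most (2.38), from 1.33 to 7.51 CPM, followed by FAXDC2 (2.28), ANK1, ZNF467, SLC26A7, the methionine sulfoxide reductase MSRB3 (2.03), GAP43, ADM2, complement C3 and CLIC3. Of the 10 largest falls, 9 held the word GGATTTC in their 3' UTR, with 4 copies in MZT1, and the tenth was PXN.

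By edgeR without the block, 0 genes passed for PXN siRNA; the smallest adjusted p was 0.0596, and 2150 genes had an unadjusted p below 0.05, against 710.4 by chance. DESeq2 called 742, and edgeR with the replicate block 4189, of which 2197 rose and 1992 fell, 294 and 198 of them at least 2-fold. Among the 172 searched genes that fell at least 2-fold in the block fit, 92 (53.5%) held GGATTTC, as did 567 of all 1907 searched falling genes (29.7%), against 7.12% of those that rose at least 2-fold and 11.8% of those not called.

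Cell division genes moved together after PXN siRNA. All 31 genes of the G2/M list were lower than in the matching control library in both replicates, with a mean log2 fold change of -0.86 (camera adjusted p = 1.3e-24, and adjusted p = 0.363 with an estimated correlation). Without the block 0 members passed among all genes and 25 fell when adjusted over the list alone; with the block 30 fell, and 31 adjusted over the list alone. AURKB (-0.98), UBE2C (-1.04), the kinetochore gene NDC80 (-1.07) and CDK1 (-0.83) fell in the block fit. G1/S and replication genes had a mean of -0.47 (adjusted p = 8.6e-11, and adjusted p = 0.363 with an estimated correlation); 24 of 34 fell with the block, 8 without and 27 with it adjusted over the list alone, among them MCM10 (-1.53) and RRM2 (-0.97). Fanconi anaemia repair genes had a mean of -0.41 (adjusted p = 9.6e-09, and adjusted p = 0.334 with an estimated correlation), and 18 of 31 fell with the block, 7 without and 19 with it adjusted over the list alone, RMI2 most (-1.79). The 4 members with GGATTTC, RMI2 among them, had a mean of -0.85. The 27 without it had a mean of -0.35, and 15 of them fell with the block.

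Interferon response genes were also lower after PXN siRNA (-0.45, adjusted p = 1.2e-07, and adjusted p = 0.143 with an estimated correlation). With the block 15 of 34 fell and 1 rose, and 10 fell and 1 rose without it adjusted over the list alone; HERC5 (-1.65), IFIT1 (-1.53) and DDX60 (-1.47) fell in the block fit. NRF2 target genes were higher (0.51, adjusted p = 3.1e-07, and adjusted p = 0.181 with an estimated correlation). With the block 17 of 24 rose and 1 fell, and 5 rose and 1 fell without it adjusted over the list alone. In the block fit the aldo-keto reductase AKR1C3 (1.46), heme oxygenase HMOX1 (1.09) and NQO1 (0.67) rose, and the thioredoxin reductase TXNRD1 fell (-0.79).

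Adhesion and cytoskeleton lists were higher after PXN siRNA, less so in replicate 2. Focal adhesion adaptors had a mean of 0.35 (adjusted p = 4.9e-04, and adjusted p = 0.363 with an estimated correlation), with 16 of 32 that rose with the block, among them the paxillin relative TGFB1I1 (1.55) and FLNA (0.52). Mesenchymal genes (0.38, adjusted p = 0.0107) had 10 that rose and 1 that fell with the block, and hemidesmosome and laminin genes (0.44, adjusted p = 0.0134) had 12 and 1; for both, adjusted p = 0.363 with an estimated correlation. SRF and actin genes (0.32, adjusted p = 0.0201, and adjusted p = 0.716 with an estimated correlation) had 12 that rose, such as the myosin light chain MYL9 (1.51), and 1 that fell. Platinum transport genes (0.29, adjusted p = 0.0277, and adjusted p = 0.334 with an estimated correlation) had 6 that rose, among them the volume-regulated channel subunit LRRC8A (0.64), and 1 that fell. In replicates 1 and 2 the means were 0.46 and 0.20 for focal adhesion, 0.55 and 0.20 for mesenchymal, 0.52 and 0.31 for hemidesmosome, 0.41 and 0.12 for SRF and actin, and 0.35 and 0.22 for platinum transport genes. Without siPXN replicate 1 the mesenchymal, hemidesmosome and SRF and actin calls were lost, the last at a mean of -0.01. The hemidesmosome and SRF and actin calls were also lost without control replicate 2, and the platinum transport call without control replicate 1 or siPXN replicate 2. Fibroblast and smooth muscle markers, at 0.74 and 0.26, missed the threshold (adjusted p = 0.0502, and adjusted p = 0.363 with an estimated correlation). Without the block, 0 members of the 5 lists passed, also adjusted over the list alone. With the block and adjusted over the list alone, 18, 10, 12, 13 and 9 rose in this order of lists, and 1 fell in each of the last 4. With the block, 17 lists passed in place of 10, the added ones being histones, RAS/ERK output, stress responses, MYC, other integrins, cholesterol synthesis and NF-kB, and 0 passed with an estimated correlation.

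**Figure D3:**
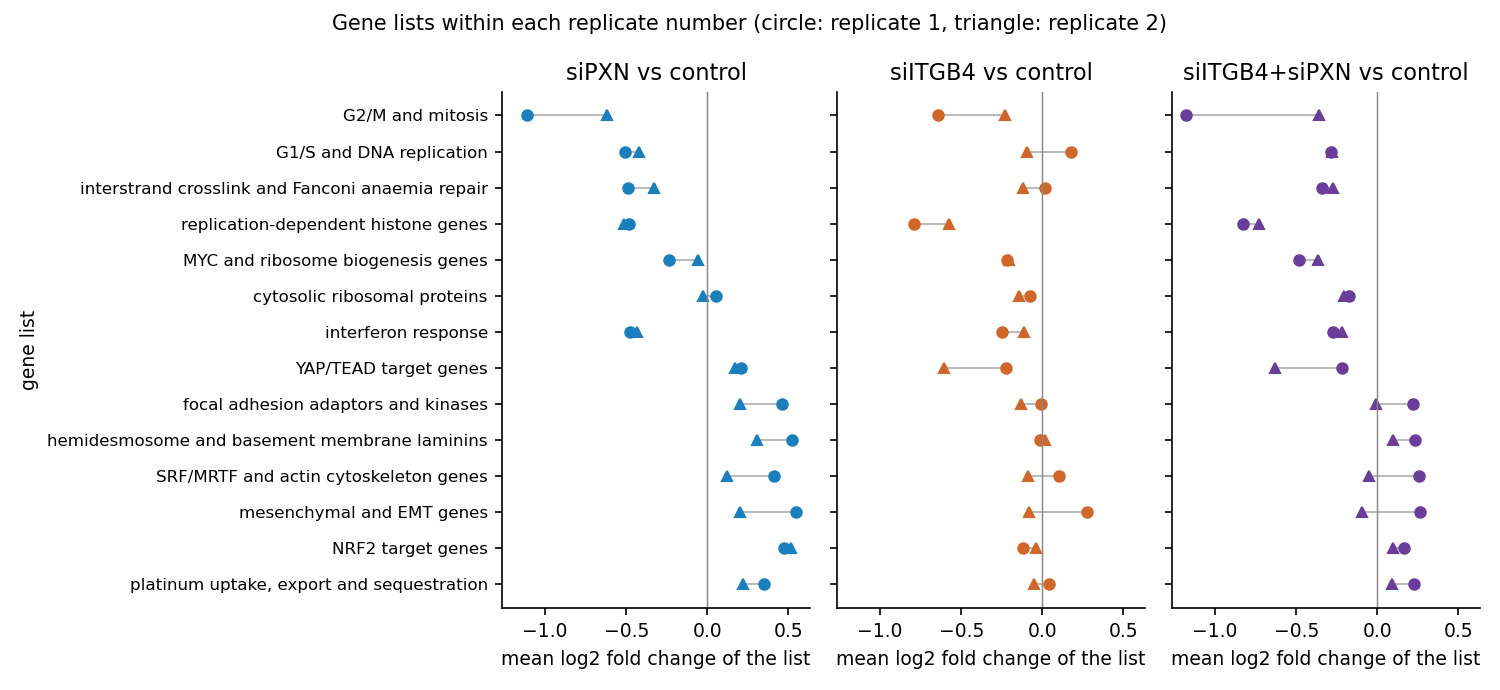
Mean log2 fold change against control of 14 gene lists within each replicate number (circles, replicate 1; triangles, replicate 2), for siPXN, siITGB4 and both siRNAs. The G2/M list is below 0 in all 6 cases, at -1.11 and -0.62 after PXN siRNA.

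The combined siRNAs against control address the joint loss of both proteins. After PXN itself, G3BP1 fell most, to 43.0 ± 1.53 CPM (log2 fold change -3.25 ± 0.14, adjusted p = 0.00186), followed by SLAIN1 (-2.99), MESDC1 (-2.71), GIPC2 (-2.64), TMEM30A, SLC25A30, LEPR (-2.37), ALDH1A3 (-2.36) and VDAC1. Of these 10 largest falls, 9 held GAGTATG, GACAACT or GGATTTC in the 3' UTR, against 1 of 9 searched largest rises, and PXN held none. For the 9, direct pairing with an siRNA is not separated from loss of the proteins. LEPR held only GGATTTC, the word of the PXN siRNA. It fell after ITGB4 siRNA alone (-2.74) and when ITGB4 siRNA was added to PXN siRNA (-2.58). For LEPR these values argue against pairing through the word it holds. IL6R rose to 213 ± 38.9 CPM (log2 fold change 2.37 ± 0.31, adjusted p = 0.0166), BMF to 79.1 ± 4.80 (log2 fold change 2.21 ± 0.26, adjusted p = 0.0133) and the cytochrome P450 gene CYP1B1 from 11.9 ± 1.25 to 51.6 ± 7.97 (log2 fold change 2.11 ± 0.21, adjusted p = 0.00752). ANKRD35 (3.13), KLHL30 (2.66), complement C3 (2.55), the mucin gene MUC21 (2.27), STXBP5-AS1, C17orf107 and IGF1 rose from below 2 CPM in control cells.

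In this comparison edgeR called 761 genes, of which 318 rose and 443 fell, 120 and 228 at least 2-fold. They include 227 of the 245 genes called after ITGB4 siRNA alone, 51 that rose and 176 that fell in both; the comparisons share the control libraries and the ITGB4 siRNA, so no chance count is given. The block gave 5847 calls (2973 up, 2874 down), all 761 among them, and DESeq2 gave 1766. Without siITGB4+siPXN replicate 1 the count was 0, its lowest, and without siPXN replicate 1 it was 367, its highest; of the 20 genes named by size, 0 to 18 stayed past the threshold. With only the groups compared in the model, 1 gene passed.

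Of the cell division genes, AURKA (log2 fold change -2.24 ± 0.27, adjusted p = 0.0133), CCNA2 (log2 fold change -1.42 ± 0.18, adjusted p = 0.0160), KIF23 (log2 fold change -1.35 ± 0.20, adjusted p = 0.0201) and TPX2 (log2 fold change -0.96 ± 0.17, adjusted p = 0.0333) fell after both siRNAs, with a G2/M list mean of -0.73 (camera adjusted p = 9.5e-12, and adjusted p = 0.795 with an estimated correlation). Adjusted over the list alone 11 members fell, and with the block 25 of 31, or 29 adjusted over the list alone. The list stood at -1.18 in replicate 1 and -0.36 in replicate 2. Its 5 members with GAGTATG, GACAACT or GGATTTC had a mean of -1.27. The 26 without a word had a mean of -0.62, and 21 of them fell with the block. MYC and ribosome biogenesis genes (-0.44, adjusted p = 0.00185, and adjusted p = 0.849 with an estimated correlation) had 1 member that fell, UTP20 (-0.84), and 19 with the block. Fanconi anaemia repair genes (-0.31, adjusted p = 0.00185, and adjusted p = 0.785 with an estimated correlation) had 2 that fell, RMI2 (log2 fold change -1.97 ± 0.18, adjusted p = 0.00676) and USP1, 6 adjusted over the list alone, and 14 that fell and 2 that rose with the block. The 6 members with a word, RMI2 among them, had a mean of -0.72. The 25 without one had a mean of -0.21, and 10 of them fell and 2 rose with the block. G1/S genes (-0.28, adjusted p = 0.00751, and adjusted p = 0.849 with an estimated correlation) had 2 that fell, CDC45 (-1.03) and MCM10 (-1.30), 4 adjusted over the list alone and 14 with the block.

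Ribosomal protein genes were slightly lower (-0.19, adjusted p = 0.00176, and adjusted p = 0.795 with an estimated correlation), with 1 that fell, RPL11 (-0.79), also when adjusted over the list alone, and 22 of 49 with the block. Histone genes (-0.79, adjusted p = 0.0123, and adjusted p = 0.849 with an estimated correlation) had HIST1H2BJ that fell (-1.77), and the YAP/TEAD list (-0.45, adjusted p = 0.0170, and adjusted p = 0.785 with an estimated correlation) had DOCK5 (-0.69), each the 1 member past the threshold by either adjustment; with the block 9 and 12 fell. Interferon genes (-0.24, adjusted p = 0.0382, and adjusted p = 0.785 with an estimated correlation) had HERC5 (-1.25) and IFIT1 (-1.56) that fell; adjusted over the list alone 5 fell and 3 rose. Leaving out 1 library lost the histone, YAP/TEAD or interferon call in some cases: histones without control replicate 2 or siITGB4+siPXN replicate 1, YAP/TEAD without siITGB4+siPXN replicate 2, interferon without control replicate 1 or siITGB4+siPXN replicate 1. Other list calls after both siRNAs were lost in such fits too.

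Marker lists of other cell types held few genes above the filter in these cultures. The 6 tested leukocyte markers were higher (camera adjusted p = 0.0138, and adjusted p = 0.785 with an estimated correlation) at a median of 2.06 CPM in control cells, and CD68, the most abundant at 8.56 ± 0.648 CPM, rose to 26.3 ± 0.898 (log2 fold change 1.62 ± 0.21, adjusted p = 0.0166). The 6 tested endothelial markers had a mean of 1.16 (adjusted p = 0.0493, and adjusted p = 0.785 with an estimated correlation; 0.0544 with the block), with 0 members called and 2 that rose adjusted over the list alone. Other single genes that passed were TXNRD1 (log2 fold change -1.42 ± 0.18, adjusted p = 0.0161), SLC7A11 (-1.20), the copper transporter SLC31A1 (log2 fold change 0.75 ± 0.15, adjusted p = 0.0408), BID (0.76), the ER degradation factor EDEM1 (-2.04), XBP1 (0.71) and HERPUD1 (1.26).

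Adding ITGB4 siRNA to cells that already had PXN siRNA gave a second estimate of its effect, from libraries that the comparison with control does not use. G3BP1 (log2 fold change -2.82 ± 0.14, adjusted p = 0.00423), LEPR (-2.58), TMEM30A (-2.47), NXPE3 (-2.38), ITGB4 (log2 fold change -2.31 ± 0.26, adjusted p = 0.0211) and VDAC1 (log2 fold change -1.94 ± 0.22, adjusted p = 0.0218) fell, and BACH2 (1.46), FNIP2 (1.24), the ceramide kinase CERK (1.22), ANKRD52 and GNPDA1 rose. The ITGB4 and VDAC1 calls were lost without either siPXN or siITGB4+siPXN library, and that of ITGB4 also without either siITGB4 library. Of 108 genes called, 7 rose and 101 fell, 4 and 79 at least 2-fold. Of these, 6 also rose and 98 also fell after ITGB4 siRNA alone, against 0.0261 and 1.36 by chance, and 0 went in opposite directions. DESeq2 called 696 and the block 3404 (1605 up, 1799 down), with all 108 among them; the count fell to 0 without siITGB4+siPXN replicate 1 and was 40 at most, without control replicate 1.

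The lists with the smallest adjusted p for added ITGB4 siRNA were YAP/TEAD targets (-0.62, camera adjusted p = 5.1e-06, and adjusted p = 0.259 with an estimated correlation), ribosomal proteins (-0.20, adjusted p = 2.0e-06, and adjusted p = 0.590 with an estimated correlation) and NRF2 targets (-0.37, adjusted p = 7.6e-06, and adjusted p = 0.259 with an estimated correlation), all lower. With the block 12, 21 and 13 of their members fell and 0 rose. A further 8 lists passed at an adjusted p of 0.0244 to 0.0357, with names and directions not given here. That made 11 in all, or 15 with the block and 0 with an estimated correlation.

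Adding PXN siRNA to cells with ITGB4 siRNA lowered PXN from 324 ± 83.3 to 31.1 ± 3.64 CPM in the block fit (log2 fold change -3.34 ± 0.17, adjusted p = 8.4e-05; without the block log2 fold change -3.38 ± 0.28, adjusted p = 0.0773). In the same fit CTSO (-2.48), TMED2 (-2.39), the ferrochelatase gene FECH (-2.17) and S100A10 (-2.13) fell, and MUC21 (1.65), LDB3, C3 (1.59), TGM5 and VIL1 rose. By edgeR without the block 0 genes passed, with 799 at an unadjusted p below 0.05 and 97 by DESeq2; with the block 542 passed (224 up, 318 down), of which 188 also rose and 296 also fell after PXN siRNA alone in that fit. G1/S genes (-0.34, camera adjusted p = 1.7e-10), G2/M genes (-0.30, 1.9e-08) and Fanconi anaemia genes (-0.26, 1.1e-07) were lower, at adjusted p = 0.708, 0.778 and 0.708 with an estimated correlation; 7 lists passed in all, 9 with the block and 0 with an estimated correlation. PXN was lower after both siRNAs than after PXN siRNA alone in the block fit (log2 fold change -0.81 ± 0.17, adjusted p = 0.00867; without the block log2 fold change -0.84 ± 0.26, adjusted p = 0.237).

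Across the 14208 genes, the effect of ITGB4 siRNA alone and on top of PXN siRNA correlated at r = 0.708 (rho = 0.687), with the same sign in 75.9% and a slope of 0.659. For PXN siRNA alone and on top of ITGB4 siRNA r was 0.669 (rho = 0.690), with the same sign in 77.1% and a slope of 0.478. The members of each pair share no library, and genes are not independent replicates. Within replicate numbers 1 and 2, r was 0.579 and 0.697 for ITGB4 siRNA and 0.617 and 0.495 for PXN siRNA. Leaving out 1 library gave 0.418 (without siPXN replicate 2) to 0.632 for ITGB4 siRNA and 0.275 (without siITGB4+siPXN replicate 1) to 0.565 for PXN siRNA, all below the values from 8 libraries. Without the low-count filter the values were 0.211 and 0.171. By DESeq2, which differs in the genes kept and in the fit, they were 0.276 and 0.225.

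**Figure D4:**
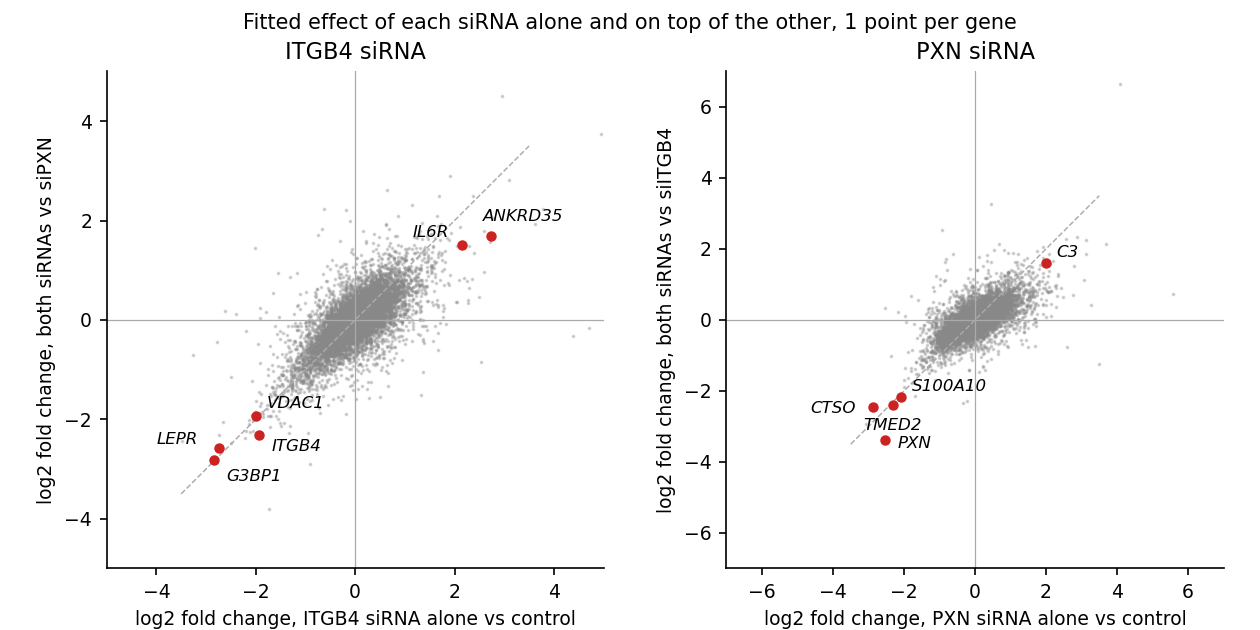
Fitted log2 fold change of each siRNA alone against control (x axis) and on top of the other siRNA (y axis), 1 point per gene, with named genes in red and the dashed line at equal effects. Across 14208 genes r is 0.708 for ITGB4 siRNA and 0.669 for PXN siRNA.

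The single siRNAs compared with each other involve no control library. LEPR (log2 fold change -2.95 ± 0.16, adjusted p = 0.00527), the kindlin gene FERMT2 (-2.75), FAM81A, MSRB3 and DBT were lower with ITGB4 siRNA, and the lectin gene CLEC7A (2.99), OSTM1 (2.68), TMED2, PXN (log2 fold change 2.54 ± 0.27, adjusted p = 0.0111) and SLC16A10 were higher; the PXN call was lost without either siPXN or siITGB4 library. Of 641 genes called, 289 were higher and 352 lower with ITGB4 siRNA; DESeq2 called 1608 and the block 5427 (2599 higher, 2828 lower), all 641 among them. The count was 0 without siITGB4 replicate 1 and 293 at most, without control replicate 2. G1/S (0.52, camera adjusted p = 2.8e-08), G2/M (0.42, 6.7e-05) and Fanconi anaemia genes (0.36, 7.0e-05) were higher with ITGB4 siRNA, and NRF2 targets (-0.58, 1.7e-06), YAP/TEAD targets (-0.62, 2.4e-04) and focal adhesion genes (-0.42, 9.3e-04) lower. None of the 10 lists past the threshold held with an estimated correlation, where the smallest adjusted p was 0.365, and fry called 2. Some of these list calls were also lost when 1 library was left out. Without siPXN replicate 1 the SRF and actin list, another of the 10, stood at 0.02 in place of -0.32.

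The interaction asks whether the combined effect departs from the sum of the single ones. By edgeR 0 genes passed without the block (108 at an unadjusted p below 0.05) and 0 with it (1437 at an unadjusted p below 0.05, smallest adjusted p 0.0802), and DESeq2 called 0. VDAC1 stood at 0.05 ± 0.30 and USP1 at 0.18 ± 0.29 on the log2 scale. At the level of lists 17 passed, led by G2/M genes (0.56, camera adjusted p = 5.8e-24, and adjusted p = 0.324 with an estimated correlation) and interferon genes (0.39, adjusted p = 2.6e-13), whose combined fall was smaller than the sum of the single falls. The interferon list was the 1 that held with an estimated correlation, at adjusted p = 0.0394 with an estimated correlation (0.160 with the block). Each control library enters both single effects, so spread in the controls moves the interaction against them. The siRNA words were also less negative in the double transfection. GGATTTC stood at -0.25 alone and -0.19 on top of ITGB4 siRNA, and GAGTATG at -0.31 alone and -0.28 on top of PXN siRNA. The target genes went the other way (PXN -0.85, ITGB4 -0.38). The dose per siRNA is not given there, so a smaller combined fall cannot be read as an interplay of the proteins.

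Genes called in the same direction by both single siRNAs numbered 0 by edgeR without the block, where the PXN siRNA comparison has 0 calls, and 125 by DESeq2. With the block 711 rose and 538 fell in both, against 294.6 and 288.8 by chance, and 334 went in opposite directions, against 585.6. Both comparisons use the same controls, and part of the excess may come from them. In 20 simulated draws with no effect at most 5 genes were called in a comparison and 2 shared, too few to compare with these counts. The covariance of the effects in those draws was at most 0.0248, against 0.0703 in the data. The measured correlation of the single effects, r = 0.313, was below the simulated 0.479 to 0.544. That range comes from the shared controls alone, and real effects of only one siRNA lower r. The correlation therefore cannot show how much the siRNAs share.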

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

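One alternative was chosen only after the result was seen: leaving out genes that hold GAGTATG or have no searched 3' UTR left 143 of the 245 genes called after ITGB4 siRNA. Limma-voom, the legacy quasi-likelihood form and the scalings by median of ratios and upper quartile left every total count of genes within 1.5 times its value and every target gene on its side of the threshold. By direction, upper-quartile scaling gave 83 rising genes in place of 53 for siITGB4 vs control and 16 in place of 7 for both vs siPXN. Depth was similar in all libraries, and each group had 2. Where libraries vary by replicate number, the model without the block loses most of its power by construction. How far the number of libraries limits power was not tested.

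With the replicate block the genes changed were 4189 for siPXN vs control, 3965 for siITGB4 vs control, 5847 for both siRNAs vs control, 3404 for both vs siPXN, 542 for both vs siITGB4, 5427 for siITGB4 vs siPXN and 1249 shared by the single siRNAs; ITGB4 (0.37) and PXN (-2.52) passed after PXN siRNA, and 17 lists passed there. DESeq2 gave 742, 936, 1766, 696, 97, 1608 and 125 in the same order, PXN at -2.53 past the threshold after PXN siRNA, and effect agreements of 0.276 and 0.225. With only the groups compared in the model the counts were 0 for siITGB4 vs control, 1 for both vs control, 0 for both vs siPXN and 7 for siITGB4 vs siPXN, and ITGB4 (-1.92 and -1.93 after ITGB4 siRNA and both) and PXN (-3.37 after both) missed the threshold, with fewer residual degrees of freedom.

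Without the low-count filter 158 genes changed after ITGB4 siRNA, 5 lists passed there, and the agreements were 0.211 and 0.171; at a minimum count of 50 these were 0.795 and 0.780. At an adjusted p below 0.01 the counts were 3, 73, 11 and 46 for siITGB4 vs control, both vs control, both vs siPXN and siITGB4 vs siPXN. An absolute log2 fold change of at least 1 left 147, 348 and 337 for siITGB4 vs control, both vs control and siITGB4 vs siPXN. An estimated correlation left 0 lists in each comparison except the interaction, with 1; fry left 2 for siPXN vs control and for siITGB4 vs siPXN and 0 in the other 5. Except where stated, the cause was not tested.

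Leaving out each library in turn, without the block, gave these ranges. Where a compared group lost a library, they also carry the difference between replicate numbers. Genes changed: 0 to 1 for siPXN vs control, 1 to 55 for siITGB4 vs control, 0 to 367 for both vs control, 0 to 40 for both vs siPXN, 0 to 293 for siITGB4 vs siPXN, and 0 throughout for both vs siITGB4, the interaction and the genes shared by the single siRNAs. ITGB4: 0.04 to 0.66 after PXN siRNA, -2.15 to -1.65 after its own and -2.17 to -1.66 after both. PXN: -2.80 to -2.23 after its own siRNA, -0.28 to 0.32 after ITGB4 siRNA, where it has no call, and -3.64 to -3.07 after both. Agreement: 0.418 to 0.632 for ITGB4 siRNA and 0.275 to 0.565 for PXN siRNA. Lists: 10 to 19 for siPXN, 3 to 7 for siITGB4 and 7 to 11 for both against control, 9 to 17 for both vs siPXN, 6 to 10 for both vs siITGB4, 7 to 13 for siITGB4 vs siPXN and 8 to 20 for the interaction.

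Among the target values above, PXN after ITGB4 siRNA reversed without control replicate 2 (-0.24) and without siITGB4 replicate 1. Within replicate numbers 1 and 2 it stood at 99.9% and 101.8% of the control library. The other 421 named gene results had 7136 alternative values, of which 0 reversed. These genes were kept for an adjusted p below 0.05 with or without the block, so a change of sign was unlikely from the outset. The block took 320 past the threshold and DESeq2 138; leaving out 1 library lost 546 calls and a model with only the groups compared 97. Of 615 list values the camera direction reversed in 7, in 5 list results that had not passed, each without 1 library: MYC genes (-0.42 to 0.15 after PXN siRNA, -0.51 to 0.10 after ITGB4 siRNA), cholesterol synthesis (-0.11 to 0.48 after PXN siRNA, -0.080 to 0.51 after both) and proteasome subunits (-0.35 to 0.028 after both). The mean itself changed sign in 12 values, these 7 among them. In 2 of the 12 the list had passed: without siPXN replicate 1, SRF and actin genes stood at -0.01 in place of 0.32 after PXN siRNA and at 0.02 in place of -0.32 for siITGB4 vs siPXN. The estimated correlation lost 33 list calls and fry 29.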

Other observations

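Of the tests reported here, those of a second word in the ITGB4 RNA, of transfection as such and of called genes without the first word, and the naming of genes from the block fit, were chosen only after the result was seen. The look at list members without the words was added after the fits, with its prediction for G2/M genes after PXN siRNA written before that value was seen. Many genes differed by replicate number, and the cause was not tested. In the fit with the block 7660 genes differed between numbers 1 and 2, 3613 higher in 2 and 4047 higher in 1. The immediate early genes FOS (log2 difference 4.32), FOSB (3.70), EGR1 (3.52) and NR4A1 (2.54) were higher in replicate 2, as were UNC5C (5.19) and the alveolar phosphate transporter SLC34A2 (2.74). KRT17 (-4.37) and KRT6A (-2.42), the protease MMP10 (-2.83), the cytokine IL32 (-2.82) and the integrin ITGB3 (-2.57) were higher in replicate 1, while the keratin KRT4 (2.65) was higher in replicate 2. Each of these differences had the same sign in all 4 groups.

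Gene lists that passed in no comparison with control without the block had these mean log2 fold changes over the 3 comparisons. Nucleotide excision repair ranged over -0.12 to 0.00 (smallest adjusted p = 0.0655), p53 targets over 0.08 to 0.27 (smallest adjusted p = 0.365), CDK inhibitors and senescence genes over 0.13 to 0.20 (smallest adjusted p = 0.583), and mitochondrial apoptosis genes over 0.11 to 0.14 (smallest adjusted p = 0.177). Oxidative phosphorylation ranged over -0.12 to -0.05 (smallest adjusted p = 0.0973), glycolysis and hypoxia over -0.14 to -0.02 (smallest adjusted p = 0.0896), and stress and unfolded protein responses over 0.14 to 0.23 (smallest adjusted p = 0.0655). NF-kB genes ranged over 0.22 to 0.38 (smallest adjusted p = 0.121), RAS/ERK output over 0.08 to 0.29 (smallest adjusted p = 0.0534), cholesterol synthesis over 0.06 to 0.18 (smallest adjusted p = 0.121) and proteasome subunits over -0.17 to -0.02 (smallest adjusted p = 0.126). In the p53 list after PXN siRNA and the lung lineage list after both siRNAs, mean and median were positive while camera gave a downward direction, and nucleotide excision repair after ITGB4 siRNA and glycolysis after PXN siRNA had a negative mean with a positive median. Epithelial junction genes ranged over -0.16 to 0.11 (smallest adjusted p = 0.121), lung lineage markers over -0.17 to 0.06 (smallest adjusted p = 0.483), fibroblast markers over 0.25 to 0.62 (smallest adjusted p = 0.0502) and other integrin subunits over 0.12 to 0.34 (smallest adjusted p = 0.106). Members without the siRNA words of the next 2 paragraphs, which were not tested as lists, ranged in the same order over -0.13 to 0.03, 0.22 to 0.46 (p53 targets: 0.29 after PXN siRNA and 0.46 after both, against 0.08 and 0.27), 0.12 to 0.29, 0.17 to 0.25, -0.13 to -0.06, -0.16 to 0.00, 0.20 to 0.31, 0.27 to 0.44, 0.18 to 0.32, 0.10 to 0.21 and -0.13 to -0.01. Without them epithelial junction genes ranged over -0.08 to 0.19 (after both 0.10, against -0.09), lung lineage markers over -0.11 to 0.20, fibroblast markers over 0.15 to 0.61 and other integrin subunits over 0.23 to 0.37. The words were chosen for their negative effect, and that choice by itself can raise these ranges.

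Genes that fell after ITGB4 siRNA may in part be direct targets of the siRNA through its seed, the short stretch of a guide strand that can pair with 3' UTRs of other transcripts. The word GAGTATG, the most negative of 16329 in the comparison with control (effect -0.31 over 1109 genes), ranked 1 in both siRNAs against PXN siRNA alone, which shares no library with it (-0.28), and 983 after PXN siRNA (-0.03). Among genes without it, the most negative unrelated word was GACAACT (-0.18 over 1001 genes), which ranked 1 in both siRNAs against PXN siRNA alone (-0.14). GACAACT starts 6 bases from GAGTATG in the ITGB4 RNA, and 0.0684% of the searched genes hold both within 20 bases. A candidate explanation is thus a longer duplex cut at more than one position. A bias by gene length or GC content is argued against as the whole cause, since removing that trend kept 89.5% of the median log2 fold change of the falling genes (-1.13 before, -1.01 after). The siRNA sequence stays open. The 91 searched falling genes without the first word may respond to loss of integrin beta 4 or follow from lowered off-target genes. Those that hold GACAACT may also pair with the siRNA directly. The rising genes stay open between the first 2 of these readings. VDAC1 holds GAGTATG, so direct pairing, a response to loss of integrin beta 4 and a consequence of lowered off-target genes all stay open for it.

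Genes that fell after PXN siRNA may likewise be seed targets. The word GGATTTC had the most negative effect of all words in the comparison with control (-0.25 over 1831 genes), ranked 1 in both siRNAs against ITGB4 siRNA alone (-0.19), which shares no library with it, and ranked 12105 after ITGB4 siRNA (0.01). It occurs 2 times in the PXN RNA, and 24.3% of the searched genes hold it somewhere in theirs, so that part of the match is weak evidence. Removing a trend on length and GC content kept 98.5% of the median fall in the fit with the block, which argues against such a bias as the whole cause. Whether the 1340 searched falling genes without the word follow from loss of paxillin is open.

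Direct pairing of that word with searched 3' UTRs is argued against as a cause of the lower G2/M genes after PXN siRNA, since 0 of 31 members hold it; the members without it are thus the whole list, and the 100% of the mean log2 fold change they keep adds no further evidence. Nor were they a matter of 1 replicate number, the smaller of the replicate means being 55.5% of the larger (-0.62 and -1.11). If control cells were not transfected, transfection might lower cell division by itself. In the fit with the block 17 of the 31 members (54.8%) differed between the single siRNAs. So did 5427 of all 14208 genes, and the share by itself says little. Of the 17, 16 were lower with PXN siRNA, while the 5427 split into 2599 higher and 2828 lower with ITGB4 siRNA. That common direction argues against transfection as the whole cause. The mean of -0.43 after ITGB4 siRNA (-0.32 in the 26 members without GAGTATG or GACAACT) leaves room for a shared part. A response to loss of paxillin and an indirect effect of other genes lowered by the siRNA remain open, and a second siRNA of another sequence against each target would separate them.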
